A study of Mus musculus with 6 samples.

How the data were processed

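Total RNA of mouse gastrointestinal stromal tumours, 3 samples from mice given vehicle and 3 from mice given imatinib, was hybridised to Illumina beadchips, 1 array per sample. Per the labels' protocols, RNA was extracted with Trizol, checked by its ribosomal peaks on a Bioanalyzer, and 200 ng was amplified and labelled with biotin using the Illumina TotalPrep kit. Groups and replicate numbers were taken from the sample titles. The sample names in the probe table's headers matched the sample descriptions, and every column of values was tied to a sample.

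The deposited probe table gives, per the file headers, an intensity for each of 45281 probes (the mean signal over its beads), the number of beads, their standard error and a detection p-value against the negative controls, with no normalization between arrays. A second deposited table gives 31492 gene-level values on a log2 scale, also not normalized. Another deposited table holds the authors' processed log2 values. Per the submitters' processing notes, Partek was used, with no version given. The scanner software is not given in the sources used here. Each processed column had the rank order of the same sample in the gene-level table and a median of 5.53, so the columns had been brought to the same distribution. The scale is log2, the values are not centred on 0 and carry no direction, and the target of that normalization stays unknown.

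The probe table names no genes. Probes were linked to the gene-level table by arithmetic: a row was taken to hold a run of neighbouring probes if the log2 of the plain mean of their signals equalled the row's value on all 6 arrays, within 8e-06 log2 units, or 6.2e-05 for values of 10 and over. All 31492 rows were matched by exactly 1 run, 22825 by a single probe and 8667 by several, with no match after arrays were exchanged within groups. Of the probes, 45277 were linked, and 4 rows with repeated identifiers were left out. In the platform annotation given for this work 21546 rows had 1 gene symbol, none had several, and 9942 rows were not listed. Names were updated through the RefSeq gene table of assembly GRCm38.p6, by gene ID for 10657 rows, accession for 5492, symbol for 2458 and a unique synonym for 3385. Another 51 rows kept the platform symbol and 9445 the deposited row name. The files name no genome build, so no coordinates are given.

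Background was corrected by normexp with parameters from the detection p-values (limma's neqc procedure, offset 16), followed by quantile normalization and log2. The offset makes folds of dim genes too small. Probes with a detection p under 0.05 on at least 3 of 6 arrays were kept, 21395 in all, and each gene was represented by its kept probe with the highest mean, which left 14713 genes. Of 86 other kept probes of called genes, 84 moved in the direction of the tested probe. The exceptions belonged to Cdk1 and Rgs3. Groups were compared with limma's lmFit and eBayes and Benjamini-Hochberg adjustment over all genes tested, with an adjusted p of 0.05 as the threshold and no block. Where all arrays of a group were below detection, the fold is given as a bound, with the dim group at the higher of its own value and the lowest detected signal of each array.

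Lists of genes, 39 with 750 entries, were written before the data were examined. The 38 with at least 5 measured genes, sex-linked markers left out, were tested with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. A preset correlation treats genes of a list as nearly independent. Of camera's 19 calls, 5 higher and 14 lower, none held with an estimated correlation (adjusted p from 0.451 to 0.719). By fry 10 lists passed, 9 of them among camera's, the exception being glycolysis (adjusted p = 0.0417), and 28 lists passed fry's mixed test, which asks for change in either direction. Neither form of fry compares a list with other genes.

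The rule for named genes was also fixed before the data were examined, except that clone names starting with SCL or ending in capital RIK were added from the deposited row names. It took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, passing over symbols that are only clones, predictions or accessions with listed prefixes (0 among the rises and 2 among the falls), always Kit, Etv1 and Ido1, up to 4 called members of each list by smallest p, and 2 members of a list that camera called without a called member. It gave 60 genes. U46068 looks like an accession, but its prefix is neither listed nor among those added, so it was kept.

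The alternatives covered background correction, normalization, the detection filter, the use of several probes, the variance model, array weights, a replicate block, the other deposited tables, each array left out, and the thresholds. A covariate for epithelial genes and the joint removal of vehicle 1 and imatinib 3 were added after seeing the data. The whole procedure was tested on simulated probe signals for this comparison, with 200 genes changed among 16892 tested and independent noise. It recovered 0 of 67 genes changed 1.5-fold, 27 of 67 changed 2-fold (40.3%) and 47 of 66 changed 4-fold (71.2%), with no wrong direction. Of 92 calls in all, 14 were members of 2 lists shifted besides the 200 genes, and 4 were unchanged genes. Camera with the preset correlation called both shifted lists and none of 36 unshifted lists, and with an estimated correlation both shifted lists were called too. With independent noise the genes of a list share no variation. The simulation could therefore not show false calls of lists whose genes vary together. Its recovery of single genes and its false gene calls likewise need not hold for arrays whose genes vary together. R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.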

Results

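Gene expression was measured in gastrointestinal stromal tumours of mice after injection of imatinib or of vehicle into the peritoneum. Gastrointestinal stromal tumour (GIST) is a sarcoma of the gut wall related to the interstitial cells of Cajal, the pacemaker cells of the gut, and it is commonly driven by an activating mutation of the receptor tyrosine kinase KIT. The mice carried the genotype that the labels write as Kit V558Δ/+, on the C57Bl/6 strain, and were 6 weeks old. Imatinib is a small-molecule inhibitor of KIT, of ABL and of the PDGF receptors. The dose and the length of treatment are not given in the labels. The comparison asks how treatment with the kinase inhibitor changes the transcripts of these tumours. There were 3 vehicle arrays and 3 imatinib arrays, each an Illumina beadchip hybridised with biotin-labelled RNA. Nothing in the labels says that the 3 samples of a group came from separate animals, so p-values measure the spread between these samples.

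The arrays were of similar median brightness, but the 95th percentile of signal was 39.9 times the background on imatinib 3 and 45.8 to 46.6 times on the others. Between 20684 and 21439 probes per array were detected above the negative controls, 45.7% to 47.3% of the probes, with a median of 43 beads behind a probe on each array. The groups did not overlap in this count, with 20684 to 20923 probes on the vehicle arrays and 21268 to 21439 on the imatinib arrays. Ddx3y and Kdm5d, which lie on the Y chromosome, had a probe detected on all 6 arrays, and none of the 4 Xist probes was detected on any. Over the 14713 genes tested, the correlation between 2 arrays ranged from 0.915 to 0.986. It averaged 0.975 within groups and 0.955 between groups, and vehicle 1 and vehicle 2 correlated at 0.945, below several pairs of opposite groups. On the first principal component, which held 60.8% of the variance, vehicle 1 lay at -60.5 and vehicle 3 at -30.7, while vehicle 2 lay at 0.983, next to imatinib 2 at 10.1. The remaining imatinib arrays lay at 32.8 and 47.3.

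**Figure D1:**
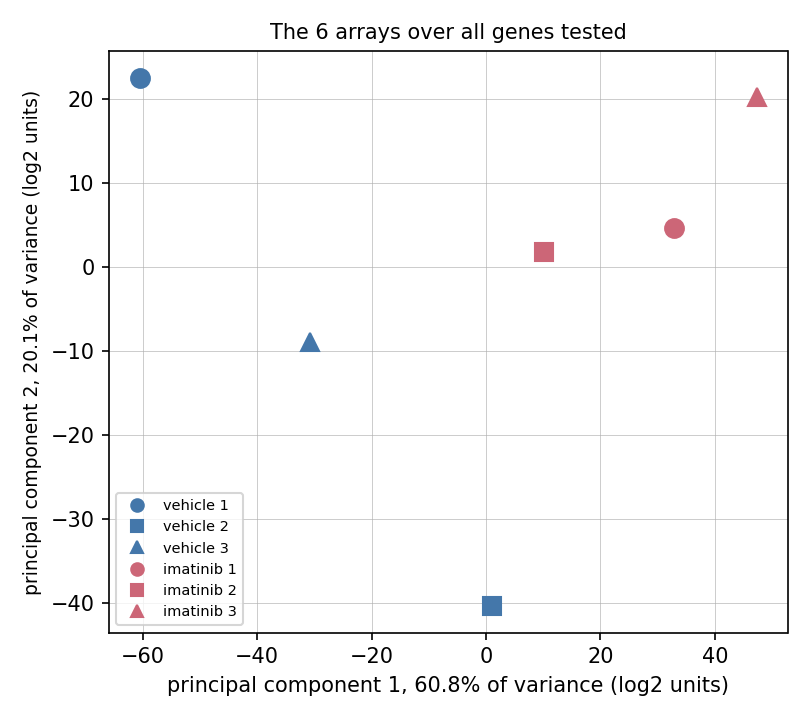
Each point is 1 array, placed by its scores on the first and the second principal component of the log2 signals of all genes tested, in log2 units. The colour gives the group and the marker the replicate number. The 3 imatinib arrays lie between 10.1 and 47.3 on the first component and the 3 vehicle arrays between -60.5 and 0.983.

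With imatinib, 9 of 26 measured genes of mitosis and 7 of 21 of the type I interferon response fell. Of 24 measured genes downstream of MAPK signalling, Ccnd1 and Etv4 fell. Among B cell, endothelial and neural markers, 2 of 15, 2 of 16 and 2 of 10 rose. As groups, these lists passed camera only with a preset correlation, and no list passed with an estimated correlation (lowest adjusted p = 0.451). Of 14713 genes, 232 passed an adjusted p of 0.05 (limma's moderated test with Benjamini-Hochberg adjustment), 77 higher and 155 lower with imatinib. Of these, 53 were at least 2-fold higher and 122 at least 2-fold lower. In all 232 genes the 3 imatinib arrays lay on one side of the 3 vehicle arrays, which follows largely from their selection by this test. Over all genes tested that share was 31.9%, against 10% by chance for a single gene. Genes vary together across the arrays, so the difference between these shares is not a test. The smallest adjusted p was 0.0338, so every call lies close to the threshold. Of the 14713 genes, 3879 had an unadjusted limma p under 0.05. Counts adjusted over a list alone, given below, apply the Benjamini-Hochberg adjustment within the list, so their threshold differs from this unadjusted one. With that many genes at a low unadjusted p, such counts are not by themselves evidence of a change in a list. No gene passed without vehicle 1, without vehicle 3, without imatinib 1 or without imatinib 3, 1355 passed without vehicle 2, and 287 without imatinib 2. Of the called genes still tested, 216 of 218 stayed called without vehicle 2 and 126 of 226 without imatinib 2.

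The largest falls held genes of several kinds. Cxcl9, a chemokine induced by interferon gamma that attracts T cells, fell 19.9-fold, from a log2 signal of 13.65 ± 0.13 (SD, n = 3 arrays) to 9.34 ± 1.56 (adjusted p = 0.0493, limma). Ngfr, the low-affinity neurotrophin receptor, fell 8.39-fold (adjusted p = 0.0338). Etv4, an ETS transcription factor induced by MAPK signalling, fell 8.06-fold (adjusted p = 0.048) and was detected on 2 of the 3 imatinib arrays. Spata19, named for its expression in the testis, fell 20.1-fold. U46068 was detected on no imatinib array and was at least 14.9-fold lower. The serotonin receptor gene Htr5b fell 8.89-fold, the lectin gene Colec11 6.29-fold, the bile acid receptor gene Gpbar1 5.81-fold, the crypt gene Olfm4 5.76-fold and the lipid synthesis regulator Thrsp 5.29-fold. Htr5b and Olfm4 were each detected on 1 imatinib array, and Spata19 and Gpbar1 on 2.

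Among the largest rises, the cytochrome P450 gene Cyp2d9 rose 6.82-fold, from 5.92 ± 0.48 to 8.69 ± 0.52 (SD, n = 3 arrays; adjusted p = 0.0377, limma). Tnfrsf13c, which encodes the BAFF receptor of B cells, rose 4.8-fold (adjusted p = 0.0338). Cxcr5, the chemokine receptor that guides B cells to follicles, rose 3.48-fold. Ccl20 and its receptor Ccr6 rose 3.77-fold and 3.1-fold. Cdkn1c, an inhibitor of cyclin-dependent kinases, rose 4.16-fold (adjusted p = 0.0338), from 8.78 ± 0.25 to 10.84 ± 0.36. Cldn5, a tight-junction gene of endothelium, rose 3.96-fold, the amylase gene Amy2 3.71-fold, the metallothionein gene Mt2 3.58-fold and the B cell receptor component Cd79a 3.13-fold. Tnfrsf13c, Cxcr5 and Cd79a were each detected on 2 of the 3 vehicle arrays. These 10 rises and the 10 falls above are the largest among the called genes under the rule for named genes. Background signal makes folds of dim genes too small.

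**Figure D2:**
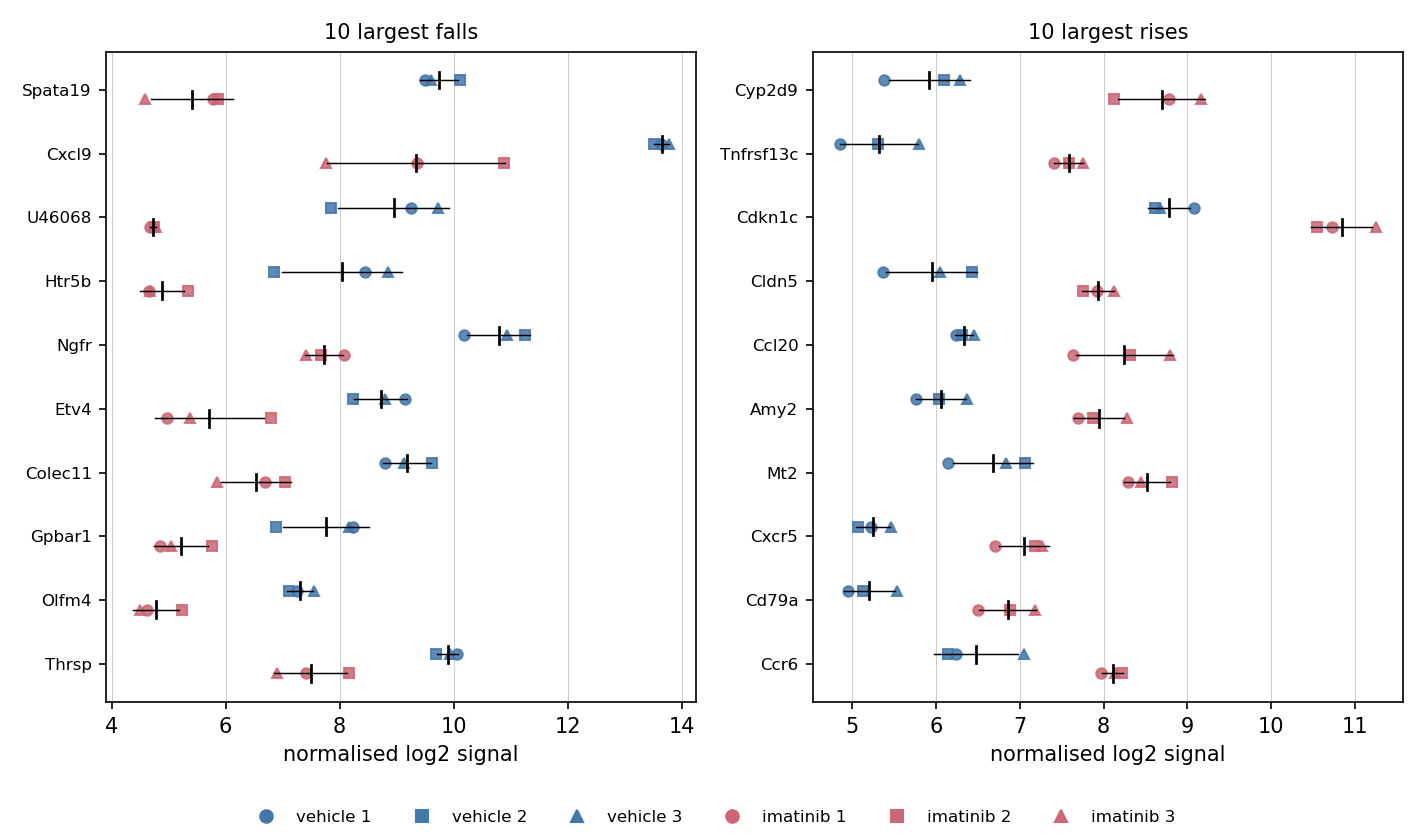
Normalised log2 signal on the horizontal axis for the 10 genes with the largest fall (left) and the 10 with the largest rise (right). Each marker is 1 array, the vertical ticks are group means and the horizontal lines are ± 1 SD over 3 arrays. In each gene the 3 imatinib arrays lie on one side of the 3 vehicle arrays, and the fall of Cxcl9 runs from 13.65 to 9.34.

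Part of the genes of cell division fell. Of 26 measured genes of G2/M and mitosis, 9 fell and 17 did not pass, none rose, and all 26 had a lower mean with imatinib. Adjusted over the list alone, 23 fell. Ccnb1, the cyclin that drives entry into mitosis, fell 2.72-fold (log2 change -1.45 ± 0.16 SE, adjusted p = 0.0338, limma), and Cdk1, its kinase partner, also fell 2.72-fold, on the probe with the higher signal, while its other probe changed by 0.18. Cenpa, the histone variant of centromeres, fell 2.33-fold, and the kinetochore gene Ndc80 2.3-fold. The median log2 change of the list was -0.97, and camera with a preset correlation gave an adjusted p of 4.62e-16, while the adjusted p was 0.451 with an estimated correlation. Among 26 genes of G1/S and DNA replication none passed on its own and all 26 had a lower mean, with a median log2 change of -0.55, and 22 fell when adjusted over the list alone. The adjusted p of that list was 5.75e-13 with camera and 0.451 with an estimated correlation. Its members with the smallest p were the helicase gene Mcm3 with a log2 change of -1.04 ± 0.18 (SE, adjusted p = 0.053) and the replication clamp gene Pcna with -0.69 ± 0.12 (adjusted p = 0.0536). For both lists fry, which asks only whether a list's genes move on balance one way, gave an adjusted p of 0.0367.

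Part of the interferon-induced genes fell. Of 21 measured genes of the type I interferon response 7 fell, none rose, 14 did not pass, and 20 fell when adjusted over the list alone. The GTPase gene Mx1 fell 4.13-fold and was detected on 2 imatinib arrays. Ifi44 fell 3.71-fold, Dhx58, a regulator of RNA sensing, 2.85-fold (log2 change -1.51 ± 0.14 SE, adjusted p = 0.0338, limma), and Irf7, the transcription factor that amplifies type I interferon, 2.81-fold. The median log2 change was -1.29 (camera adjusted p = 9.26e-15, adjusted p = 0.451 with an estimated correlation, fry adjusted p = 0.0367). In the interferon gamma list, Cxcl9 fell, the other 14 of 15 members did not pass, and all 15 had a lower mean, and 9 fell when adjusted over the list alone. The median log2 change was -1.26, with a camera adjusted p of 5.98e-07, an adjusted p of 0.473 with an estimated correlation and a fry adjusted p of 0.0898, which did not pass. Relative to its mean over the 6 arrays, this list lay at 0.167 on imatinib 2, -1.08 on imatinib 1 and -1.66 on imatinib 3, in log2 units.

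Members of the MHC class I list fell and none of the class II list passed. In the class I list 3 of 17 members fell, 14 did not pass, none rose, all 17 had a lower mean, and 14 fell when adjusted over the list alone. Tapbp, the chaperone that loads peptides onto class I molecules, fell 2.53-fold (adjusted p = 0.0338, limma), the class I gene H2-T10 2.03-fold and the peptide-trimming protease gene Erap1 2.03-fold. The list's median log2 change was -0.74 (camera adjusted p = 7.7e-09, adjusted p = 0.451 with an estimated correlation, fry adjusted p = 0.0418). In the 11-gene MHC class II list 9 members had a lower mean and 2 a higher mean. Its camera adjusted p was 0.0128, with an adjusted p of 0.581 with an estimated correlation and a fry adjusted p of 0.21. H2-DMa changed by -1.27 ± 0.30 (SE, adjusted p = 0.0749), and H2-Ob, which B cells express, by 0.82 ± 0.17 in the opposite direction (adjusted p = 0.0611). Adjusted over the list alone, 6 members fell and 2 rose.

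The B cell markers Cd79a and Vpreb3 rose, and no T cell marker passed. In the B cell and plasma cell list 2 of 15 members rose, 13 did not pass, 14 had a higher mean, and 9 rose when adjusted over the list alone. Cd79a rose 3.13-fold, and Vpreb3, a component of the pre-B cell receptor, was at least 2.19-fold higher, since it was detected on no vehicle array. The median log2 change was 0.98 (camera adjusted p = 7.55e-06, adjusted p = 0.451 with an estimated correlation, fry adjusted p = 0.0367). No T cell gene passed among 19, and 16 had a lower mean. The T cell median log2 change was -0.29 (camera adjusted p = 0.000857, adjusted p = 0.451 with an estimated correlation, fry adjusted p = 0.0787), and 5 fell when adjusted over the list alone. Cd8a changed by -1.23 ± 0.27 (SE, adjusted p = 0.0656) and the adaptor gene Skap1 by -0.90 ± 0.19 (adjusted p = 0.0646). Among 12 genes of cytotoxic effectors none passed, with a median of -0.52, a camera adjusted p of 0.00193, an adjusted p of 0.451 with an estimated correlation and a fry adjusted p of 0.0787. Adjusted over the list alone, 7 fell and 1 rose. The granule genes Ctsw and Nkg7 changed by -0.86 ± 0.16 (SE, adjusted p = 0.0547) and -1.02 ± 0.23 (adjusted p = 0.0733). Another granule gene, Prf1, changed by 0.74 ± 0.19 in the opposite direction (adjusted p = 0.0811). In the dendritic cell list Xcr1, a chemokine receptor of cross-presenting dendritic cells, was at least 1.81-fold lower and was detected on no imatinib array, while 11 of 12 members did not pass. That list had a median of -0.77, a camera adjusted p of 0.00398, an adjusted p of 0.451 with an estimated correlation and a fry adjusted p of 0.0528, and adjusted over the list alone 7 fell and 2 rose.

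**Figure D3:**
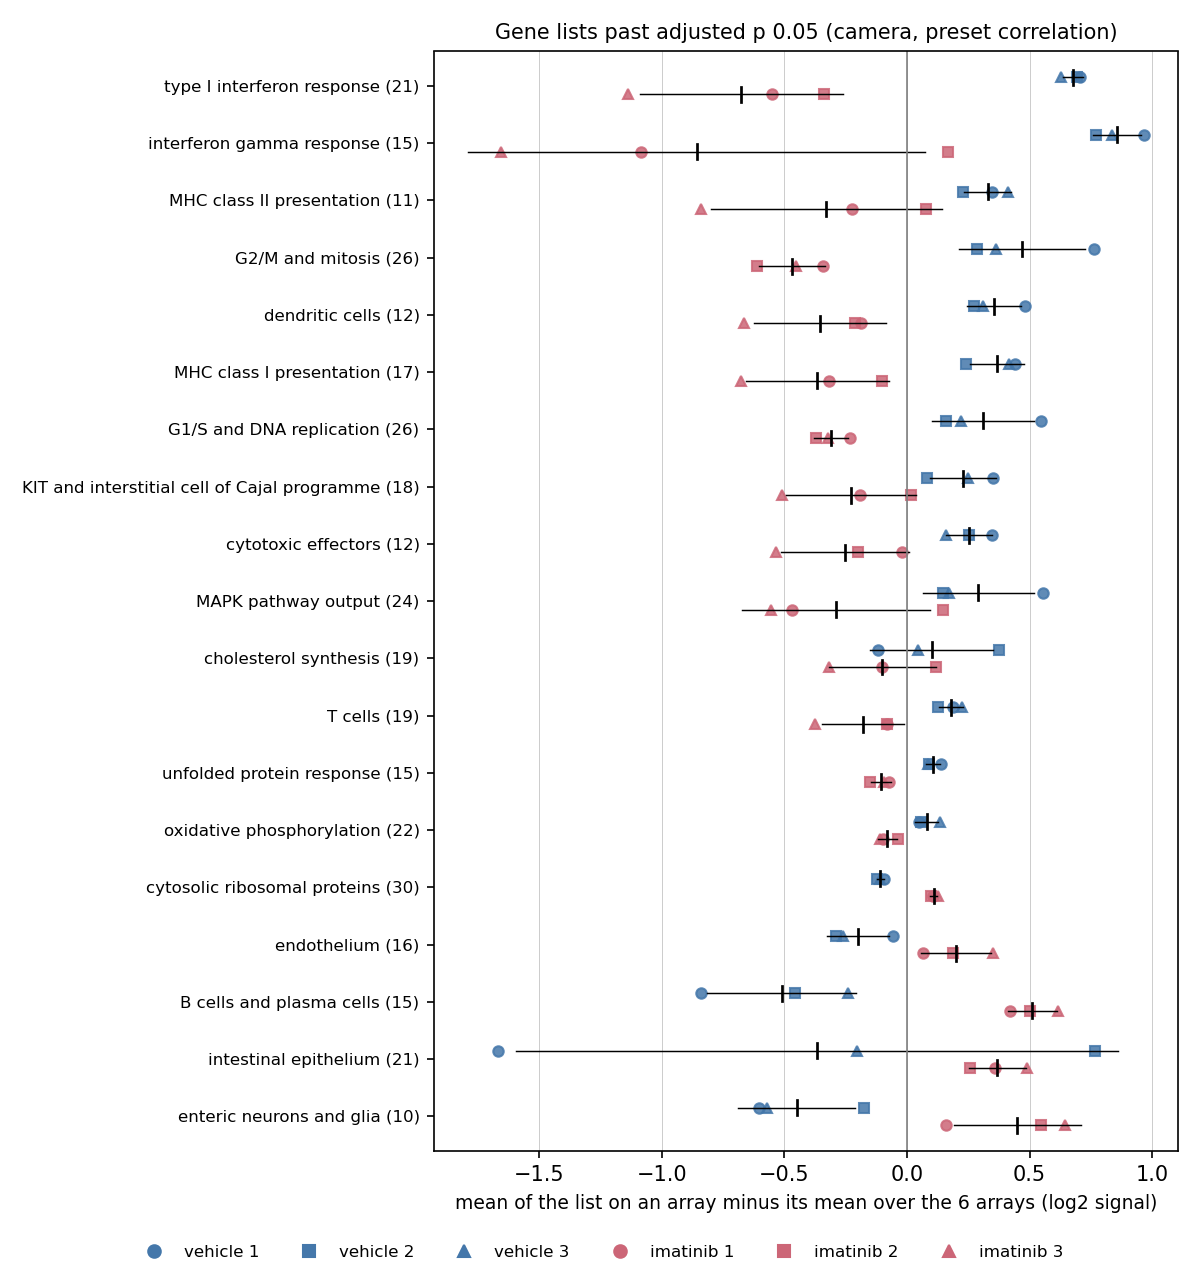
Rows are the 19 gene lists past an adjusted p of 0.05 by camera with a preset correlation, with the number of measured genes in brackets. The horizontal axis is the mean log2 signal of a list on an array minus its mean over the 6 arrays. Each marker is 1 array, vertical ticks are group means and lines are ± 1 SD over 3 arrays. In the interferon gamma list imatinib 2 lies at 0.167 and imatinib 3 at -1.66, and in the intestinal epithelium list vehicle 1 lies at -1.67 and vehicle 2 at 0.769.

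At the threshold used, neither Kit, the drug target, nor any other gene of its programme list passed. Kit itself had a log2 signal of 14.24 ± 0.20 with vehicle and 13.94 ± 0.50 with imatinib (SD, n = 3 arrays), a log2 change of -0.30 ± 0.26 (SE, adjusted p = 0.485, limma). Across the alternatives its change ranged from -1.05 to -0.00313, and it passed only with array weights (adjusted p = 0.0415), where 7585 genes passed. Etv1, the ETS factor that maintains the interstitial cell of Cajal programme, changed by 0.09 ± 0.21 (adjusted p = 0.806), with values from -0.66 to 0.37 across the alternatives. Kit and Etv1 each had 3 kept probes, of which only the brightest was tested. Their mean change was -0.11 on the tested probes and -0.55 with the mean of each gene's probes (95% interval -1.59 to 0.49). None of the 18 measured genes of the KIT and interstitial cell of Cajal list passed, and 13 had a lower mean. Its median log2 change was -0.53, its camera adjusted p 0.0128, its adjusted p 0.475 with an estimated correlation and its fry adjusted p 0.147. Adjusted over the list alone, 5 fell and 1 rose. Plat, which encodes tissue plasminogen activator, changed by -0.99 ± 0.18 (SE, adjusted p = 0.053) and passed in 12 of 23 alternatives, among them the one without vehicle 2, and the glypican gene Gpc6 by -1.32 ± 0.25 (adjusted p = 0.0557). Of 24 genes read as output of the MAPK pathway 2 fell, 22 did not pass, none rose, and 4 fell and 1 rose when adjusted over the list alone. Ccnd1, the D-type cyclin that carries growth signals into the cell cycle, fell 2.36-fold (log2 change -1.24 ± 0.18 SE, adjusted p = 0.0417), beside Etv4. The median of that list was -0.50, with a camera adjusted p of 0.00846, an adjusted p of 0.536 with an estimated correlation and a fry adjusted p of 0.191. In that list 17 members had a lower mean and 7 a higher mean. Relative to its mean over the 6 arrays, the list lay at 0.149 on imatinib 2 and 0.148 on vehicle 2, in log2 units, so the groups overlapped.

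Ido1, which encodes the enzyme that starts tryptophan breakdown to kynurenine, had a log2 signal of 10.75 ± 0.89 with vehicle and 7.94 ± 0.83 with imatinib (SD, n = 3 arrays). The log2 change of -2.81 ± 0.56 (SE) did not pass (adjusted p = 0.0593, limma), although all 3 imatinib arrays lay below all 3 vehicle arrays. Of 23 alternatives it passed in 2 by limma and not in the other 21. These were the one without vehicle 2 (log2 change -2.33, adjusted p = 0.0469), where 1355 genes passed, and array weights (-2.31, adjusted p = 0.00315), where 7585 did. None of the 7 measured genes of tryptophan catabolism passed. Their median was 0.27 and their mean -0.17, with a camera adjusted p of 0.455 in the upward direction, and Ido1 alone fell when adjusted over the list alone. Published work on this mouse model concerns Ido, so the tryptophan list is not independent evidence of a direction.

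Some markers of other cell types in the gut wall rose. In the list of enteric neurons and glia 2 of 10 members rose, 8 did not pass, and 9 had a higher mean. Sox10, a transcription factor of glia, rose 2.63-fold (log2 change 1.39 ± 0.18 SE, adjusted p = 0.0411, limma), and Nos1, the nitric oxide synthase of inhibitory motor neurons, 2.03-fold. The list's median was 1.19 (camera adjusted p = 4.46e-05, adjusted p = 0.451 with an estimated correlation, fry adjusted p = 0.0367), and 9 rose and 1 fell when adjusted over the list alone. The member that fell was Ret, with a change of -1.36 ± 0.37 (SE, limma adjusted p over all genes = 0.0948). In the endothelium list 2 of 16 rose and 14 did not pass. Cldn5 rose 3.96-fold, and Sox17, an arterial transcription factor, 2.2-fold. Its median was 0.55, its camera adjusted p 0.00257, its adjusted p 0.475 with an estimated correlation and its fry adjusted p 0.0552, and 11 rose and 3 fell when adjusted over the list alone. Those 3 were Eng, Lyve1 and Plvap. They changed by -1.47 ± 0.29, -1.26 ± 0.45 and -0.91 ± 0.22 (SE, limma adjusted p over all genes = 0.0581, 0.146 and 0.0779).

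The intestinal epithelium list varied within the vehicle group more than between groups. It lay at -1.67 on vehicle 1, 0.769 on vehicle 2 and -0.204 on vehicle 3, in log2 units from its mean over the arrays, and between 0.257 and 0.489 on the imatinib arrays. Olfm4 fell, the other 20 of 21 members did not pass, and 19 had a higher mean. Adjusted over the list alone, Olfm4 alone fell. The median of 1.01 had a camera adjusted p of 0.0145, an adjusted p of 0.719 with an estimated correlation and a fry adjusted p of 0.507, and without vehicle 1 the median was 0.40 with a camera adjusted p of 0.428. With the mean of this list as a covariate, 49 genes passed instead of 232, 38 of them among the 232. The mesothelium list did not pass (median 0.76, camera adjusted p = 0.0818), although all 10 members had a higher mean. It lay at -1.42 on vehicle 1, and it passed in 5 of 23 alternatives, among them the one without vehicle 3 (median 1.33, adjusted p = 6.2e-05). The division, B cell and neural lists had their most extreme vehicle value on that array too, at 0.761, -0.838 and -0.604.

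No gene passed in the lists of translation and metabolism that camera called. All 30 cytosolic ribosomal protein genes had a higher mean and none passed alone, and 2 rose when adjusted over the list alone. Their median log2 change was 0.20 (camera adjusted p = 3.43e-05, adjusted p = 0.451 with an estimated correlation, fry adjusted p = 0.00226). Rps3 changed by 0.53 ± 0.11 (SE, adjusted p = 0.0614, limma) and Rps19 by 0.49 ± 0.11 (adjusted p = 0.0641). In the oxidative phosphorylation list 17 of 22 genes had a lower mean and none passed, over all genes or adjusted over the list alone, with a median of -0.16, a camera adjusted p of 0.0134, an adjusted p of 0.451 with an estimated correlation and a fry adjusted p of 0.0418. The complex IV gene Ndufa4 changed by -0.77 ± 0.17 (SE, adjusted p = 0.0674) and cytochrome c, Cycs, by -0.65 ± 0.17 (adjusted p = 0.0837). The lists of the unfolded protein response and of cholesterol synthesis both had a camera adjusted p of 0.0491, with adjusted p of 0.451 and 0.69 with an estimated correlation, fry adjusted p of 0.0367 and 0.401, and medians of -0.18 and -0.31. In the unfolded protein response list Pdia6 changed by -0.95 ± 0.17 (SE, adjusted p = 0.053) and Trib3 by -1.10 ± 0.22 (adjusted p = 0.0582), and 2 of 15 genes fell when adjusted over the list alone. In the cholesterol list Insig1 changed by -0.85 ± 0.20 (SE, adjusted p = 0.0745) and Sqle by -0.96 ± 0.27 (adjusted p = 0.0977), and none of 19 passed over the list alone. The cholesterol call was lost without vehicle 2, imatinib 1 or imatinib 3 (camera adjusted p = 0.573, 0.0517 and 0.174), with medians of -0.22, -0.30 and -0.10. The unfolded protein response call was lost without vehicle 2 or imatinib 2 (camera adjusted p = 0.156 and 0.179), with medians of -0.21 and -0.14.

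The other 19 lists did not pass, with camera adjusted p between 0.0818 and 0.902. Single members moved in 4 of them. Plk2, a p53-induced kinase gene, rose 1.96-fold in the p53 target list, the heat shock gene Hspa1a 2.21-fold in the stress list and Amy2 3.71-fold in the exocrine pancreas list, while Thrsp fell 5.29-fold in the adipocyte list (limma). Medians of the remaining cell type lists were -0.36 for macrophages, 0.14 for regulatory T cells, 0.74 for neutrophils, 0.35 for mast cells, 0.49 for smooth muscle, -0.12 for fibroblasts and matrix, 0.54 for red cells, -0.11 for adipocytes and 0.97 for exocrine pancreas. Imatinib 3 stood apart in the neutrophil list, at 2.63 against 0.357 and -0.904 on imatinib 1 and 2, and in the red cell list, at 1.77 against -0.354 and -0.659, in log2 units from the mean over the arrays. The neutrophil list passed only with no detection filter (adjusted p = 0.00825). Without imatinib 1 the macrophage list passed (median -0.26, adjusted p = 0.0359), and without vehicle 2 the smooth muscle list (median 0.67, adjusted p = 0.0323). For macrophages the mean, 0.0998, had the opposite sign, as for fibroblasts and matrix at 0.0685. The regulatory T cell median of 0.14 stood against a downward camera direction. Of the pathway lists, medians were 0.18 for FOXO targets, -0.15 for glycolysis, -0.08 for apoptosis regulators (mean 0.0305), -0.05 for p53 targets, 0.31 for the hypoxia response, 0.11 for the stress list, -0.04 for lysosome and autophagy and 0.09 for ribosome biogenesis.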

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

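The epithelium covariate and the removal of vehicle 1 with imatinib 3 were chosen after seeing the data, and all other settings before. The 39 named genes past the threshold had the same direction in each of the 23 refits that measured them, which for left-out arrays follows from groups that do not overlap, and none passed in all, so the side of the threshold depends on the setting. Of 232 genes (77 higher, 155 lower), the count became 484 (147 and 337) with cyclic loess, 435 (126 and 309) with every probe tested, 408 (127 and 281) with the mean of a gene's probes, 429 (153 and 276) with eBayes with trend, 432 (157 and 275) with trend and robust, 362 (94 and 268) with the gene-level table, 385 (121 and 264) with the authors' processed values, and 1668 (773 and 895) at an adjusted p of 0.10. Array weights gave 7585 (4270 and 3315). There 1 array, vehicle 3, had a weight of 19.6 against 0.292 to 1.78 for the others, and the weights stopped short of their tolerance. The epithelium covariate gave 49 (15 and 34). With no detection filter 0 genes passed by limma (0 and 0), with 5183 at an unadjusted p under 0.05 among 29516 tested, and without vehicle 1 and imatinib 3 0 passed (0 and 0), with 1841 at an unadjusted p under 0.05. The cause was not tested. Leaving out 1 array gave 0 to 1355 genes, 0 to 767 higher and 0 to 588 lower, with 2402 to 4865 at an unadjusted p under 0.05.

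Replicate numbers did not pair the arrays: deviations from the group means of same-numbered arrays correlated at -0.112, -0.308 and 0.0188, and 0 of 3 vehicle arrays correlated best with their own number. With the replicate block 0 genes passed by limma (0 higher and 0 lower), with 2900 at an unadjusted p under 0.05, and 19 lists passed.

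Of camera's 19 lists, 13 passed in every refit with the preset correlation and none changed direction. The count of lists was 0 with an estimated correlation and 10 with fry, and leaving out 1 array gave 18 to 20. The lists of the KIT programme, MAPK output, cholesterol synthesis, cytotoxic effectors, intestinal epithelium and unfolded protein response were lost in at least 1 refit. Red cells, not past the threshold, turned to a median of -0.55 and a downward call (adjusted p = 0.0395, range 0.0395 to 0.927) without vehicle 1 and imatinib 3. The excess of within-group over between-group correlation was 0.0201, and 0.0189 with no normalization. Background limits dim genes: the median signal of a probe was 50.7 to 57.1 against a background of 36.7 to 41.4.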

Other observations

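The genes in this paragraph and the next were chosen after their values were seen, from the 232 called genes outside the lists and the rule. Several further genes with known roles in mitosis were lower with imatinib (limma, 3 arrays a group): the spindle gene Ckap2, detected on 1 imatinib array, changed by -2.32 ± 0.22 in log2 signal (SE), the mitotic kinase gene Pbk by -2.06 ± 0.23, the midbody gene Cep55 by -1.33 ± 0.17 and the spindle gene Aspm by -1.34 ± 0.21. Ccnd3, a second D-type cyclin beside Ccnd1, changed by -1.02 ± 0.16. Psat1 and Mthfd2, enzymes of serine synthesis and of mitochondrial one-carbon metabolism, changed by -0.98 ± 0.13 and -1.09 ± 0.14. Whether these pathways changed as groups was not tested.

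Among immune genes outside the lists, the receptor gene Cd40 changed by -1.44 ± 0.14. Il34, a ligand of the CSF1 receptor, changed by -1.58 ± 0.26. The endothelial adhesion gene Selp changed by 1.11 ± 0.13 and Edn1, which encodes endothelin, by 1.41 ± 0.22.

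The tests of tumour cell share, of lymphoid tissue, of the main cell type and of gut wall muscle below were chosen only after the values they use were seen. Imatinib treatment is the biological difference that the design names, and it stays open in each pattern. The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 232 genes and the highest of the others 1, so 1 of 10 splits gave as many. At an unadjusted limma p under 0.05 the real split gave 3879 genes. The split that exchanges vehicle 2 and imatinib 2 gave 2602. For the lists past camera's threshold, the real split gave 19 and the highest of the others 20, and 3 of 10 splits gave as many.

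The first pattern is the fall of mitosis genes and of type I interferon genes, of which 9 of 26 and 7 of 21 passed, with medians of -0.97 and -1.29. A lower share of tumour cells cannot be told apart from it: the mean change of Etv1 and Kit was -0.11 (95% interval -0.81 to 0.59) on the probes tested but -0.55 (-1.59 to 0.49) with the mean of each gene's probes, a version added after the result was seen, and the median of the KIT list was -0.53. With the epithelium list as a covariate the medians were -0.79 and -1.33, 81.9% and 103% of their size, and both lists kept their camera calls at the preset correlation (without the covariate both had an adjusted p = 0.451 with an estimated correlation), while called members went from 9 to 2 and from 7 to 1. With median scaling in place of quantile normalization at least 101% of both medians was kept. Uneven epithelium and quantile normalization are therefore unlikely as the whole cause of the medians.

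The second pattern is the rise of B cell genes, of which 2 of 15 passed, with a median of 0.98. More lymphoid tissue of all kinds would raise T cell genes too, if neither the number of T cells in the tumour itself nor expression within T cells changed. The T cell median was -0.29, with a standard error over members of 0.11. This error treats the genes as independent and does not measure the spread between arrays. The T cell list mean lay between 0.127 and 0.226 on the vehicle arrays and between -0.375 and -0.0819 on the imatinib arrays. The T cell list did not rise on the imatinib arrays. Fewer T cells in the tumour itself, or lower expression within T cells, could hide a gain of lymphoid tissue, so the test cannot decide. Tissue rich in B cells alone, such as a lymphoid follicle taken along with some tumours, could give the same pattern and was not tested. Expression within B cells also stays open.

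The third pattern is the higher median of the enteric neuron and glia list, 1.19, with 2 of 10 members passing, and of the endothelium list, 0.55, with 2 of 16 passing, while Ret, Eng, Plvap and Lyve1 had negative values. A lower share of the main cell type alone would raise markers of every other type alike. In a test that left endothelium out, the neuron and glia median lay 1.31 ± 0.36 (SE over members) above that of fibroblasts. It lay 1.55 ± 0.48 above that of macrophages. These errors treat the genes of a list as independent and do not measure the spread between arrays. The medians did not rise alike, but a change within fibroblasts or macrophages could give the same differences, so the test cannot decide. More gut wall muscle on the imatinib arrays may bring enteric neurons along. The smooth muscle list had a median of 0.49, with a standard error over members of 0.17, and a fry p of 0.446. Its mean lay between -0.746 and 0.325 on the vehicle arrays and between -0.0305 and 0.428 on the imatinib arrays. More gut wall muscle therefore cannot be told apart from a change within these cells.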
